A study of Mus musculus with 5 samples.

How the data were processed

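Neutrophils were sorted from bone marrow, blood and lung, labelled with hashtag antibodies and loaded, per the labels, as about 24000 cells per lane (8000 from each tagged sample) on 10x Chromium with version 3 chemistry. The deposited data held 3 gene expression libraries (naive, AT3, AT3-gcsf) and 3 hashtag count files in 2 hashtag samples; the naive and AT3 hashtag libraries were deposited as 1 sample and the AT3-gcsf library as another. The gene expression matrices held raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger 4.0.0 and bcl2fastq 2.20.0.422 against mm10, per the file headers and the submitters' notes, over 32285 genes and with called barcodes only. The hashtag files held raw counts per hashtag and barcode as deposited; the program that made them, and whether molecular identifiers were collapsed, are not given in the sources used here. No values were normalised before deposition.

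Each hashtag file was joined to the library whose called barcodes it labelled. Of the called barcodes of the naive, AT3 and AT3-gcsf libraries, 95.7%, 97.4% and 94.1% carried a dominant tag in the file joined to them, against at most 0.672% in any other file. The plan had ranked barcodes by all hashtag counts; the entry for unmapped reads made that ranking ambiguous, so named tags alone were used, and ranking by their counts gave the same pairing. The joined files named MHTO3, MHTO4 and MHTO5 for naive, MHTO7, MHTO8 and MHTO10 for AT3, and MHTO3, MHTO4 and MHTO5 for AT3-gcsf. No label ties a tag to a tissue, so tissues were not assigned and the planned edgeR test between tissues was not run. No paired analysis was possible because no label ties a population of one library to a population of another.

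Cells were demultiplexed with HTODemux (Seurat 5.3.0 in R 4.3.3, positive quantile 0.99, clara clustering, seed 42). Single-tag cells numbered 7297 in naive (94.3%, Clopper-Pearson interval 93.8 to 94.8), 7376 in AT3 (94.1%, 93.5 to 94.6) and 10011 in AT3-gcsf (92.5%, 91.9 to 92.9). Tag doublets were 402, 431 and 762 and untagged cells 39, 33 and 55. Cells with fewer than 200 genes or at least 10% mitochondrial counts were removed (33, 18 and 31), as were doublets computed by Scrublet as implemented in scanpy 1.11.5, with an expected rate of 8% (49, 79 and 34). Scrublet called 38.6%, 45.1% and 27.9% of the tag doublets it was given, and 0.671%, 1.07% and 0.359% of the other cells.

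The remaining 7215, 7279 and 9946 cells were clustered together: counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and a graph of 15 neighbours was partitioned by Leiden (igraph 0.11.9) at resolution 0.5 without batch correction, giving 10 clusters. The partition depended on the number of processor threads, and a single thread was used. A cluster was kept when neutrophil markers made up at least 10% of its counts, a minimum set after the clusters were seen. This removed 1 mixed cluster led by Scgb1a1, Sftpc and Cd74, with 218, 99 and 49 cells. Its share ran from 0.928% to 6.00% of naive, 0.199% to 3.19% of AT3 and 0.177% to 0.976% of AT3-gcsf populations. In it all 10 promyelocyte or granulocyte-monocyte progenitor markers reached 20 CPM, and Elane was at 745 CPM against 5.26 in the other clustered cells. Early cells of the neutrophil lineage may therefore have been left out with that cluster. The compared cells are thus sorted cells other than that cluster. They numbered 6997, 7180 and 9897 and held 25926216, 46741741 and 86252733 counts. Most clusters came mainly from 1 library and can be that library as well as a cell state.

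Counts were summed per library and per tagged population and scaled to the total (CPM). A gene was compared when it reached 20 CPM in the higher sum, and counted as different at a log2 ratio of at least 1 in size after adding 5 CPM to both values. With 1 library per condition no p-value was computed. CPM carry exact Poisson intervals and ratios of very low counts a conditional binomial interval; these cover counting error only. For each gene the 3 populations of a library were set against the 3 of the other, giving 9 pairs, and a gene was noted when all 9 pairs had the same direction, which 10% of genes not picked for their size show by chance if populations are exchangeable. These need not be, since populations of different libraries resembled each other to different degrees. This measure was not in the plan and was added once the tags were seen to name no tissue. Populations of a library share its lane and are not replicates. Leaving out 1 population sets 2 of a library against 3 of the other, so a ratio can shift because a population is missing from 1 side only.

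Before the data were examined, 21 gene lists were fixed: primary granule, secondary granule, gelatinase granule, cell cycle, mature circulating, interferon-stimulated, myeloid-suppressor associated, G-CSF and STAT3 targets, chemokines and cytokines, NF-kB feedback, immediate-early and dissociation, glycolysis and hypoxia, oxidative phosphorylation, NADPH oxidase, chemotaxis and adhesion receptors, ageing and clearance, antigen presentation, apoptosis and survival, granulopoietic transcription factors, protein folding and endoplasmic-reticulum stress, and lipid metabolism. Each was given by the median log2 ratio of its members at 20 CPM or more, where at least 3 were left, and the percentile of that median among 10000 random lists of the same size matched on expression in 20 bins. A list outside the central 95% was called; 27 of 63 list comparisons were. Lists share members, so their calls are not independent. Markers of 17 cell classes were fixed in the same way. Named genes were, also by a rule fixed before, the 12 highest and 12 lowest log2 ratios without mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, T cell receptor and predicted genes, up to 4 members of each list, and Csf3r, Csf3, Ly6g, S100a8 and S100a9. The rule for genes named between populations of a library (at least 20 CPM and 2-fold above both others) was set after the data were seen. Mki67 was named although it lay below that minimum.

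Tests of explanations were written down before their statistics were computed, except the ratio of the counts with equal weight for the populations. Values per cluster and per population had been looked at before any of them was written, so none was blind to the data. Gene positions came from GENCODE vM21 on GRCm38; all 153 named genes were matched by identifier, 151 of them with the same symbol. The calculations were tested on simulated data with known answers: of 200 genes changed 4-fold, 197, 198 and 200 were called the right way in the 3 comparisons and 0 unchanged genes were called. Of 100 random lists, 5%, 3% and 4% fell outside the central 95%, and ratio intervals covered 94.0%, 95.6% and 94.4% of the true values. These checks cover the arithmetic only and cannot show whether scaling to the total suits the data. In AT3 against naive, 85 genes were counted as higher and 246 as lower, but 184 and 38 under TMM scaling. Genes of a random list are not picked for shared regulation, so these percentages need not hold for lists of co-regulated genes.

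Alternatives covered the pseudocount (1 and 20 CPM), the minimum (5 CPM), scaling (TMM of edgeR 4.0.16, and totals without the 20 most abundant genes), no cell filter, computed doublets kept, all single-tag cells, cells thinned to 1500 counts, a rule that the top tag hold at least 80% and 20 of the tag counts, a stricter HTODemux quantile, clusters at resolution 0.3 and 1, and the immature-like clusters left out. The last was planned as the largest mature clusters and run as all clusters whose mature markers exceeded their immature ones. The immature markers share Camp, Ngp, Ltf, Lcn2, Cybb and Cd177 with the secondary granule list, so that list is not independent of this choice of cells. Alternatives that take in cells outside the clustering cannot drop mixed-cluster cells among those. Chosen after seeing the data were equal weight for the tagged populations, each of the 9 populations left out in turn, the cluster led by Apoe and Siglecf left out, counts of genes on one side in all 9 pairs only, and the genes shared by the 2 comparisons against naive under every alternative. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.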

Results

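Single-cell gene expression was measured in neutrophils sorted from the bone marrow, blood and lung of female mice in 3 conditions. Naive C57BL/6J mice were set beside mice bearing AT3 tumours, a mouse mammary carcinoma line, and mice bearing tumours of AT3-gcsf, by its name a G-CSF form of that line. G-CSF, the product of Csf3, is the main growth factor of the neutrophil lineage. Each condition had 1 gene expression library, so there were no replicates and no spread between mice could be estimated. The naive, AT3 and AT3-gcsf libraries held 7738, 7840 and 10828 cell barcodes and 32089597, 54424062 and 99703525 UMI counts. After demultiplexing and filtering, 6997, 7180 and 9897 cells were compared, with a median of 2737, 4630.5 and 7531 UMIs. Intervals are 95% and exact (Poisson for CPM, counts scaled to the same total per sum; Clopper-Pearson for shares) and cover counting error only. Condition and 10x lane cannot be told apart, because each condition filled 1 lane. Genome positions are on mm10 (GRCm38) from the GENCODE vM21 gene records.

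Each library carried 3 hashtags, which are named by number only, so its 3 populations are given by tag number and no tissue is assigned. Whether a tag number used in more than 1 library marks the same tissue is not given in the sources used here. In the naive library, MHTO4 cells stood apart by genes of secondary granules, the antimicrobial stores filled during neutrophil maturation. All 11 measured members of that list were at least 2-fold higher there than in both other populations. Camp, the cathelicidin precursor, was at 21134 CPM against 849 and 434 in MHTO3 and MHTO5, Ltf, lactoferrin, at 6596 against 322 and 149, and Ngp at 24416 against 1251 and 535. Elastase (Elane) was at 43.7 CPM against 1.03 and 2.12, and the proliferation marker Mki67 at 16.9 against 1.47 and 1.06. Mki67 lay below the 20 CPM minimum and is named as an exception. Of 4 measured cell cycle genes, 0 were at least 2-fold higher in MHTO4 than in both other populations. Naive MHTO5 cells had 416 genes at least 2-fold above both other populations. They included the neutrophil-attracting chemokine Cxcl2 (7431 CPM against 228 and 72.3), Acod1, the itaconate-producing enzyme (2347 against 60.2 and 20.9), and thrombospondin 1 (Thbs1, 4231 against 182 and 100.4). Of the measured members, 14 of 15 NF-kB feedback genes and 11 of 14 chemokine and cytokine genes were higher in MHTO5. Naive MHTO3 cells had 219 such genes, among them Prr5l (143 CPM against 29.1 and 10.3), Rgs2, a brake on G-protein signalling (764 against 198 and 193), and Klf2 (1637 against 484 and 289). The interferon-induced gene Ifit3b was at 94.8 CPM there against 18.2 and 13, and 6 of 19 interferon-stimulated genes were higher. Haemoglobin transcripts took 0.129% of counts in MHTO3, against 0.0290% in MHTO4 and 0.00872% in MHTO5.

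The AT3 library held populations with much the same leading genes. AT3 MHTO7 cells had Camp at 10586 CPM against 1361 and 1104 in MHTO8 and MHTO10, Ltf at 4966 against 872 and 611, and the mitotic gene Ube2c at 44.7 against 1.05 and 6.04, with 9 of 10 secondary granule and 1 of 5 cell cycle genes higher. AT3 MHTO8 cells had Cxcl2 at 6596 CPM against 162 and 78.6, Ptgs2, the inducible prostaglandin synthase, at 719 against 17.1 and 5.77, and the immediate-early gene Egr1 at 271 against 5.94 and 2.47. There, 10 of 13 NF-kB feedback and 9 of 12 chemokine and cytokine genes were higher. AT3 MHTO10 cells had Gpr146 at 98.5 CPM against 23.9 and 10.8, Prr5l at 185 against 54.9 and 31.7, and 5 of 21 interferon-stimulated genes higher. Of the genes higher in a population than in both others of its library, 88 were shared by naive MHTO4 (196) and AT3 MHTO7 (99), 237 by naive MHTO5 (416) and AT3 MHTO8 (257), and 78 by naive MHTO3 (219) and AT3 MHTO10 (117). The AT3-gcsf library differed: no population had a raised secondary granule list (0 of 10 genes in each), and Camp lay between 208 and 957 CPM. Its MHTO3 and MHTO4 were much alike (Pearson correlation 0.986 on the log2 scale, at most 0.906 within the other libraries). Few genes could therefore stand 2-fold above both others in either. Camp was at 504, 957 and 208 CPM and Ngp at 2886, 3914 and 2170 in MHTO3, MHTO4 and MHTO5. AT3-gcsf MHTO5 cells had 191 higher genes, including Cxcl2 (5012 CPM against 86.1 and 75.5), Hilpda, a lipid droplet protein (455 against 12.5 and 10.2), and the EGF-receptor ligand amphiregulin (Areg, 170.2 against 1.84 and 1.82). Of these, 168 were among the genes higher in AT3 MHTO8 and 172 among those higher in naive MHTO5. In AT3-gcsf MHTO4 the 3 higher genes were Apoe, Acot1 and Apoc2, with Apoe at 379 CPM against 104 and 91.7. The 1 in MHTO3 was the predicted gene Gm34455, named after its value was seen.

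**Figure D1:**
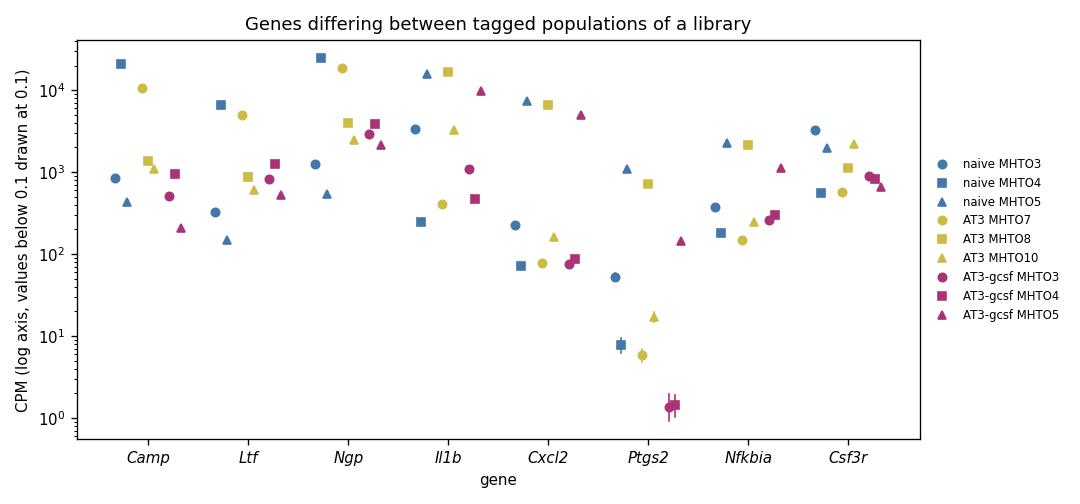
CPM (log axis) of 8 genes in each of the 9 tagged populations, 1 point per population with its exact Poisson interval, coloured by condition with the tag as marker shape. Camp reached 21134 CPM in naive MHTO4 and 10586 in AT3 MHTO7 but at most 957 in AT3-gcsf, and Cxcl2 lay at 7431 in naive MHTO5, 6596 in AT3 MHTO8 and 5012 in AT3-gcsf MHTO5.

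Neutrophils of AT3 tumour-bearing mice had far more transcript of a few secreted and membrane proteins than naive ones. Wfdc17, a secreted WAP-domain protein (chromosome 11, 83703991 to 83706268), was at 10669 CPM (10639.5 to 10699) against 587 (578 to 597), a log2 ratio of 4.17. Prok2, a secreted chemoattractant peptide (chromosome 6, 99711299 to 99726392), was at 579 CPM (572 to 586) against 24.1 (22.2 to 26.0), log2 ratio 4.33. Igfbp6, which binds insulin-like growth factors (chromosome 15, 102144362 to 102149511), was at 404 CPM against 14.2 (4.41), and the interferon-inducible membrane protein Ifitm1 (chromosome 7, 140967221 to 140969825) at 8646 against 777 (3.47). These 4 genes were higher in every AT3 population than in every naive population, as were the metalloreductase Steap4 (3.36), the glutathione-cleaving enzyme Ggt1 (2.99), uridine phosphorylase Upp1 (2.83), the lipase Lipg (2.78), the mitochondrial outer-membrane protein Tspo (2.37) and the protease inhibitor Stfa2 (2.2). Saa3, an acute-phase protein, was at 73.5 CPM against 3.70 (3.17), with AT3 populations from 6.79 to 140.5 and naive ones from 0.080 to 9.09. Without naive MHTO4 the log2 ratios of Igfbp6, Wfdc17, Ifitm1 and Steap4 were 3.73, 3.34, 2.69 and 2.62, and without naive MHTO3 they were 5.07, 4.99, 4.05 and 4.16. Without naive MHTO3, Stfa2 stood at 3.26; without AT3 MHTO7, Igfbp6 and Saa3 stood at 5.02 and 3.91; without AT3 MHTO8, Saa3 stood at 2.30. Areg was at 27.5 CPM against 0.887 (2.46), but 0.02 without AT3 MHTO8 and 3.18 without AT3 MHTO7.

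Among genes lower in AT3 than in naive cells, Thbs1 (chromosome 2, 118111876 to 118127133) was at 87.1 CPM (84.4 to 89.8) against 1191 (1177 to 1204), log2 ratio -3.70. It was at 4231 CPM in naive MHTO5 and 242 in AT3 MHTO8, and at most 182 and 6.94 in the other populations of the 2 libraries. The ratio depended on the populations summed: it was -0.78 without naive MHTO5, -4.54 without naive MHTO4, -2.92 without AT3 MHTO7 and -6.91 without AT3 MHTO8. Some lower genes did not overlap between the populations of the conditions: Nat8l, which makes N-acetylaspartate (-1.92), the integrin Itgb7 (-1.96, and -2.58 without naive MHTO4) and the adhesion molecule Ncam1 (-1.82, and -0.69 without naive MHTO4). The scavenger receptor Olr1 (-2.19) was at -0.07 without naive MHTO5, -2.95 without naive MHTO4 and -3.20 without AT3 MHTO8. Elane was at 1.99 CPM against 21.9 (-1.94) but at 0.09 on the log2 scale without naive MHTO4, which held most of what the compared naive cells had, and the eosinophil-type ribonuclease gene Ear2 (-1.89) was at -0.12. The mixed cluster left out of the comparison had Elane at 745 CPM. The anti-apoptotic paralogs Bcl2a1a, Bcl2a1b and Bcl2a1d (-2.14, -2.16 and -1.98), whose reads are hard to assign among them, were at -0.43, 1.09 and 0.75 without naive MHTO5. Their values were -2.94, -3.06 and -2.84 without naive MHTO4, and -3.0, -4.41 and -3.07 without AT3 MHTO8; Bcl2a1b was at -1.44 without AT3 MHTO7.

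By gene list, AT3 cells had interferon-stimulated and glycolytic genes above the genes of like expression and NF-kB feedback and adhesion genes below them. Each list is given by its median log2 ratio, the same median less that of all genes, and its percentile among 10000 random lists matched on expression. The interferon-stimulated list stood at 0.37 (0.71 less all genes, percentile 100), with 16 of 21 members above 0, led by Gbp2, a GTPase against intracellular microbes (136 CPM against 35.6, log2 1.79), Ifitm3 (1.49) and the nucleic-acid sensor Zbp1 (1.29). Rsad2 and Cmpk2 were among the members below 0. Of the 21, 3 were higher in all 9 pairs of populations and 0 lower. Markers of interferon-responding neutrophils, which overlap the list, summed to 1974, 411 and 2247 CPM in naive MHTO3, MHTO4 and MHTO5. In AT3 MHTO7, MHTO8 and MHTO10 they summed to 866, 1662 and 2249 CPM. Without naive MHTO4, the naive population with the fewest interferon transcripts, the interferon-stimulated list stood at -0.22 with percentile 98.7, Gbp2 at 1.08 and Zbp1 at 0.88. The glycolysis and hypoxia list stood at 0.21 (0.55, percentile 100), with the glycolytic enzyme Pfkl at 21.3 CPM against 8.49. Of its 18 measured members, 1 was at least 2-fold higher, Hilpda (1.01, and -2.00 without AT3 MHTO8). The 2 at least 2-fold lower were Vegfa (-1.53, and 0.42 without naive MHTO5) and Ndrg1 (-1.20, and -0.75 without naive MHTO3). The lipid list stood at 0.27 (0.61, percentile 99.7), with the fatty-acid carrier Fabp5 at 301 CPM against 74.3 (1.95), the droplet protein Plin2 at 196 against 109.9 (0.81) and Acsl1, which activates fatty acids, at 42.5 against 132 (-1.53). The list was at -0.44 (percentile 63.4) without naive MHTO4, 0.06 (96.3) without AT3 MHTO8 and -0.24 (71.9) over all singlets. NF-kB feedback genes stood at -0.62 (-0.28, percentile 0.92), and at -1.27 without naive MHTO4, 1.24 without naive MHTO5, 0.11 without AT3 MHTO7, -2.04 without AT3 MHTO8 and -0.41 (percentile 34.7) without AT3 MHTO10. It also lost its place outside the central 95% over all singlets (-0.57, percentile 2.85) and in thinned cells (-0.47, 2.84). Chemotaxis and adhesion receptors stood at -0.56 (-0.22, percentile 0.16), with Cxcr4, which retains neutrophils in marrow, at 242 CPM against 565 (-1.21), the integrin chain Itgax at 8.86 against 31.7 (-1.40) and the chemokine receptor Cxcr1 at 40.1 against 13.7 (1.27). That list lost its place outside the central 95% without naive MHTO3 (-0.19), naive MHTO4 (-0.51), naive MHTO5 (-0.27) or AT3 MHTO7 (-0.26), over all singlets (-0.34, percentile 26.3) and in thinned cells (-0.37, 3.50). Cxcr4 was at -0.74 without naive MHTO5, -0.60 without AT3 MHTO7 and -2.20 without AT3 MHTO8, Itgax at -2.13 without naive MHTO4, -0.97 without naive MHTO5 and -0.94 without AT3 MHTO7, and Cxcr1 at 0.66 without naive MHTO4.

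The mature circulating list stood at -0.44 (-0.10, percentile 0.26) but at 0.08 under TMM scaling, 0.25 without naive MHTO5, -0.15 without naive MHTO3, -0.08 without AT3 MHTO7 and -0.36 (percentile 6.39) over all singlets. Myeloid-suppressor associated genes stood at 0.04 (0.38, percentile 97.6), with Wfdc17, Prok2 and Ifitm1 as above, but at -0.01 without naive MHTO3, -0.57 without naive MHTO4, 1.69 without naive MHTO5 and -1.12 without AT3 MHTO8. In thinned cells, without the immature-like clusters and with equal weight for the populations that list lay inside the central 95%, at 0.02, -0.08 and -0.15 (percentiles 94.6, 91.6 and 70.9). G-CSF and STAT3 targets stood at 0.21 (0.55, percentile 99.8), with Socs3, the feedback inhibitor of that pathway, at 309 CPM against 134 (1.17) and the cytokine receptor Il4ra at 149 against 67.3 (1.09). This list stood at 0.01 without naive MHTO3, -0.51 without naive MHTO4, 0.93 without naive MHTO5, 0.18 without AT3 MHTO7 and -0.34 without AT3 MHTO8. Socs3 was at 0.32 without naive MHTO4, 1.82 without naive MHTO5 and 0.58 without AT3 MHTO10, and Il4ra at 0.53 without naive MHTO4 and 0.78 without AT3 MHTO10. The G-CSF receptor Csf3r was at 1100.1 CPM against 1622, Csf3 itself at 7.0 against 7.14, Ly6g at 693 against 416, and S100a8 and S100a9, the calprotectin genes, at 155012 and 160204 against 120238 and 133580.3. Naive Ly6g was at 782 CPM in MHTO4 against 95.5 and 52.9 in the other populations. S100a8 with S100a9 took 12.5% to 37.3% of counts in naive and 25.2% to 39.4% in AT3 populations. The other 13 lists lay within the central 95% of matched lists, with medians from -0.60 (ageing and clearance) to 0.10 (primary granule). Among them were secondary granule (-0.33), gelatinase granule (-0.33), cell cycle (-0.23), immediate-early (-0.07), oxidative phosphorylation (-0.31), NADPH oxidase (-0.06), antigen presentation (-0.10), granulopoietic transcription factor (-0.33) and protein-folding (-0.40) genes, all of which turned positive under TMM, and apoptosis (-0.50) and chemokine (-0.45) genes, which lay near 0 under it. Of these 13 lists, 12 lay outside that range, on either side, under at least 1 of the 19 alternatives. Ageing and clearance genes did so under 10, with medians over all 19 from -1.25 to -0.10; they were at -0.70 and -1.25 without naive MHTO3 and MHTO4, -0.56 and -0.97 without AT3 MHTO7 and MHTO10, -0.72 in thinned cells and -0.68 with equal weights. Chemokines did so under 7, at -0.71, -1.11 and 1.30 without naive MHTO3, MHTO4 and MHTO5, -2.25 without AT3 MHTO8, -0.66 over all singlets, -0.52 in thinned cells and -0.71 with equal weights. Secondary granule genes did so under 6, at -0.74, 2.45 and -0.74 without naive MHTO3, MHTO4 and MHTO5, -1.64 without AT3 MHTO7, -0.47 in thinned cells and 0.70 without the immature-like clusters. Only 3 of 10 primary granule and 5 of 20 cell cycle genes were measured, and their medians were the values of Serpinb1a and Ran. Over all singlets, which keep the mixed cluster, the primary granule and cell cycle lists stood at -0.99 and -0.82 (percentiles 0.04 and 0.16).

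In all, 85 of 3925 genes were at least 2-fold higher and 246 at least 2-fold lower in AT3 than in naive cells. Of these 331, 163 (49.2%) lay on one side in all 9 pairs of populations; over all genes and any size of difference 15% did, where chance gives 10%, a value that does not apply to genes picked for their size. The split depended on scaling: the median of all genes was -0.34, TMM moved it by 0.53, and the counts became 184 higher and 38 lower, or 160 and 205 with the 20 most abundant genes left out of the totals. Single log2 ratios are therefore to be held against the median of -0.34. The count was 828 without naive MHTO4 and 521 without AT3 MHTO8.

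Cells from AT3-gcsf mice differed from naive ones by more genes, and the acute-phase gene Saa3 led. Saa3 (chromosome 7, 46711998 to 46715700) was at 3896 CPM (3883 to 3909) against 3.70 (3.00 to 4.52), a log2 ratio of 8.81, with 2583 to 4949 CPM in the AT3-gcsf populations. Prok2 was at 1471 CPM against 24.1 (5.67), Wfdc17 at 25846 against 587 (5.45), Igfbp6 at 612 against 14.2 (5.01) and Ifitm1 at 22896 against 777 (4.87). Spint1, an inhibitor of membrane serine proteases (chromosome 2, 119237362 to 119249527), had 12869 counts against 2, a CPM ratio of 1934 with a counting interval of 535 to 15972. The cysteine-protease inhibitors Stfa2 (4.41) and Cstdc5 (4.01), Ggt1 (4.52), the caspase Casp6 (4.31), the calcium-binding copine Cpne8 (4.08) and Lipg (3.72) followed, and all 12 genes were higher in every AT3-gcsf population than in every naive one. Stefin and cystatin paralogs share sequence, so their separate values are uncertain. Without naive MHTO3 the log2 ratios of Wfdc17, Igfbp6, Ifitm1, Stfa2 and Cstdc5 were 6.27, 5.66, 5.46, 5.48 and 4.87; without naive MHTO4 those of Wfdc17, Igfbp6 and Ifitm1 were 4.62, 4.33 and 4.09.

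Thbs1 was the lowest, at 24.8 CPM (23.7 to 25.8) against 1191, log2 ratio -5.33 (-2.41 without naive MHTO5, -6.16 without naive MHTO4, -7.66 without AT3-gcsf MHTO5). Camp (chromosome 9, 109847379 to 109849617) was at 551 CPM (546 to 556) against 10529 (-4.24), and the ratio was -0.23 without naive MHTO4 and -5.00 without AT3-gcsf MHTO4. The secreted glycoprotein Crispld2 (17.3 CPM against 229.7, -3.39), smooth-muscle actin Acta2 (-3.01), the antiviral kinase Cmpk2 (-3.0) and the small GTPase Rab44 (-2.99) were lower in all 9 pairs with no single population deciding the size. Acta2 is a stromal gene and need not come from neutrophils: lung endothelial, epithelial and stromal markers were at 116 to 233 CPM in naive and 32.3 to 36.2 in AT3-gcsf populations. Rsad2, the antiviral protein viperin, was at 14.6 CPM against 155 (-3.03, and -3.71 without naive MHTO4). Olr1 (-3.13) was at -3.89 without naive MHTO4 and -1.0 without naive MHTO5, and Bcl2a1a (-3.10) at -3.91 and -1.39. Bcl2a1b (-3.97) and the orphan nuclear receptor Nr4a3 (-3.26) were at -0.72 and 0.19 without naive MHTO5, -4.88 and -4.15 without naive MHTO4, and -4.77 and -4.29 without AT3-gcsf MHTO5. Ptgs2os2, a non-coding transcript near Ptgs2, was at -2.86, and -0.75 without naive MHTO5, -3.69 without naive MHTO4 and -3.99 without AT3-gcsf MHTO5.

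Lipid and glycolytic genes stood above genes of like expression in AT3-gcsf, and ageing, adhesion and NF-kB feedback genes below them. The lipid list had a median of 1.32 (1.70 less all genes, percentile 100), with 5 of 8 members at least 2-fold higher, among them Fabp5 (359.9 CPM against 74.3, log2 2.2) and the lipid carrier Apoe (198 against 52.1, 1.83), and with Acsl1 (28.5 against 132, -2.03) lower. Apoe was at 1.12 without naive MHTO4, 0.83 without AT3-gcsf MHTO4, the population with most of it, 0.92 without the cluster led by Apoe and Siglecf and 1.02 over all singlets. Macrophage markers, which include Apoe, were also highest in AT3-gcsf MHTO4 (1836 CPM against 1269 and 1023). Glycolysis and hypoxia genes stood at 0.65 (1.03, percentile 100), with 6 of 19 at least 2-fold higher and 2 lower. The 2 lower ones were Vegfa (-1.90, and 0.05 without naive MHTO5) and Ndrg1 (-1.83). Pfkl was at 44.9 CPM against 8.49 (1.89) and Hilpda at 185 against 41.1 (2.04), the latter at -1.48 without AT3-gcsf MHTO5, 1.2 without naive MHTO4, 4.59 without naive MHTO5 and 2.64 without AT3-gcsf MHTO4. Ageing and clearance genes stood at -1.12 (-0.74, percentile 0.395), with 7 of 11 at least 2-fold lower. Cxcr4, which marks aged neutrophils homing to marrow, was at 85.6 CPM against 565 (-2.65; -3.74 without AT3-gcsf MHTO5), and the checkpoint ligand Cd274 at 13 against 60.3 (-1.86; -2.71 without naive MHTO4, -0.08 without naive MHTO5, -2.98 without AT3-gcsf MHTO5). Chemotaxis and adhesion receptors stood at -1.02 (-0.64, percentile 0.010), with the integrin chain Itgal at 111 CPM against 428 (-1.90) and Cxcr1 at 56.1 against 13.7 (1.71; 1.09 without naive MHTO4). That list was at -0.35 (percentile 11.3) without naive MHTO3 and -0.84 (7.67) without naive MHTO4.

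Secondary granule genes stood at -1.94 (-1.56, percentile 0), with 8 of 11 at least 2-fold lower, but at 1.52 without naive MHTO4. There Ngp went from -2.04 to 1.72, and Cybb, the NADPH oxidase core, from -2.59 to 0.11. Without the immature-like clusters the list was at 0.88, but these were picked by markers that overlap it. The one led by Camp, Ltf and Ngp held 1021 naive and 29 AT3-gcsf cells, and the other 6 and 2430. The value of 0.88 is therefore partly set by that choice of cells. NF-kB feedback genes stood at -1.57 (-1.19, percentile 0), but at 0.80 without naive MHTO5, -2.40 without naive MHTO4 and -2.34 without AT3-gcsf MHTO5. Chemokines and cytokines stood at -0.94 (-0.56, percentile 0.965), but at 1.69 without naive MHTO5, -1.67 without naive MHTO4, -0.69 and -0.52 without AT3-gcsf MHTO3 and MHTO4, -2.51 without AT3-gcsf MHTO5, and -0.85 (percentile 4.73) without the cluster led by Apoe and Siglecf. Within it the monocyte attractant Ccl2 was at 36.2 CPM against 1.35 (2.70; 0.75 without AT3-gcsf MHTO5) and the interleukin-1 antagonist Il1rn at 79.2 against 504 (-2.60; -1.37 without naive MHTO5, -3.31 without naive MHTO4, -3.27 without AT3-gcsf MHTO5). Mature circulating genes stood at -0.67 (-0.29, percentile 0.22), and at -1.27 without naive MHTO4 and -0.11 without naive MHTO5. Csf3r was at 769 CPM against 1622 (-1.07; -0.43, -1.76 and -0.97 without naive MHTO3, MHTO4 and MHTO5, -0.93 without AT3-gcsf MHTO5). Csf3 was at 1.34 against 7.14 CPM, Ly6g at 704 against 416, and S100a8 and S100a9 at 141249 and 143156 against 120238 and 133580.3. In naive populations Ly6g ran from 52.9 to 782 CPM, and S100a8 with S100a9 took 12.5% to 37.3% of counts.

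The interferon-stimulated list stood at -0.63 against naive (percentile 10.9), inside the central 95%, with 8 of 19 members at least 2-fold lower; it stayed below 0 with the 20 most abundant genes left out (-0.44) and under TMM (-0.07). Under 5 of the 19 alternatives it lay below that range: -0.97 in thinned cells, -1.03 without the immature-like clusters, -0.98 with equal weights, -1.32 without naive MHTO4 and -1.02 without AT3-gcsf MHTO5. The other 12 lists inside that range had medians from -0.71 (apoptosis) to 0.09 (G-CSF and STAT3 targets). They included NADPH oxidase (0.07) and, with medians that turned positive under TMM, antigen presentation (-0.45), cell cycle (-0.48), protein folding (-0.53), gelatinase granule (-0.47), immediate-early (-0.35), myeloid-suppressor (-0.21), oxidative phosphorylation (-0.18), primary granule (-0.25) and transcription factor (-0.31) genes. In the antigen presentation list Cd74, the class II invariant chain, was at 8.80 CPM against 50.3; B cell marker transcripts, which do not belong to neutrophils, were at 8.22 to 15.1 CPM in AT3-gcsf populations and 82.0 to 211 in naive ones. Of these 13 lists, 9 lay outside the range under at least 1 alternative, antigen presentation under 5: -1.02 with a 5 CPM minimum, -1.21 over all singlets, -1.05 under the 80% rule for tags, -1.23 without the immature-like clusters and -1.60 without naive MHTO4. Only 4 of 10 primary granule and 4 of 20 cell cycle genes were measured. Over all singlets, which keep the mixed cluster, the cell cycle list stood at -1.28 (percentile 0.91).

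In all, 224 of 4095 genes were at least 2-fold higher and 869 lower in AT3-gcsf than in naive cells. Of these 1093, 817 (74.7%) lay on one side in all 9 pairs of populations, and over genes with any size of difference 40.0% did, where chance gives 10% for genes not picked by size. The median of all genes was -0.38; TMM moved it by 0.62 and gave 562 higher and 270 lower, and totals without the 20 most abundant genes gave 391 and 837. Without naive MHTO4 the count was 1443, against 828 for AT3 and naive.

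**Figure D2:**
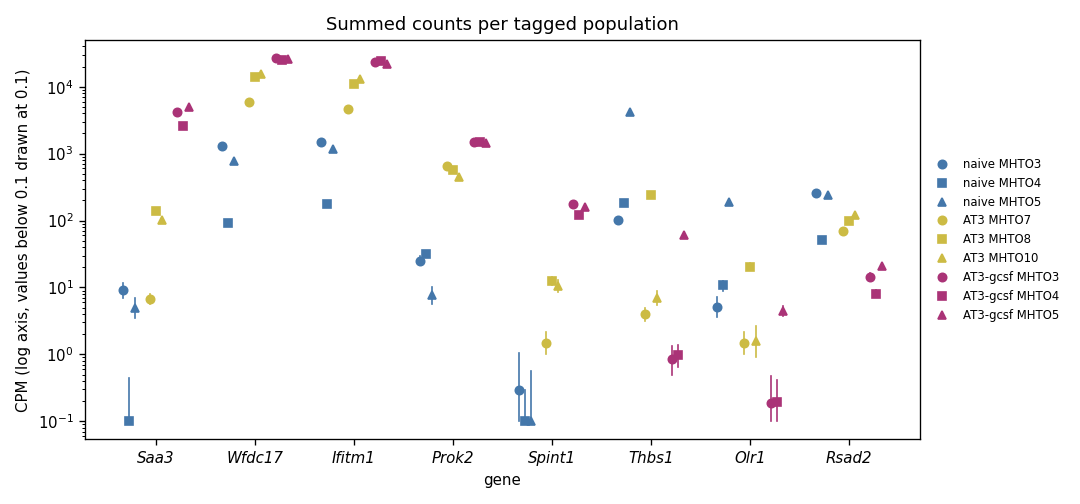
CPM (log axis; values below 0.1 drawn at 0.1) of 8 genes in the 9 tagged populations, 1 point per population with its exact Poisson interval, naive in blue, AT3 in yellow and AT3-gcsf in purple. Saa3 lay at 2583 to 4949 CPM in AT3-gcsf, 6.79 to 140.5 in AT3 and 0.080 to 9.09 in naive populations, and Rsad2 at 8.05 to 20.6 in AT3-gcsf against 69.7 to 120.1 in AT3.

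Set against AT3, the AT3-gcsf cells had more Saa3, Stfa2, Cstdc5 and Csta2 and a lower interferon-stimulated list. Saa3 was at 3896 CPM against 73.5 (log2 5.64; 4.90 without AT3 MHTO7, 6.5 without AT3 MHTO8), Cpne8 at 82.2 against 0.770 (3.92), Spint1 at 149 against 7.25 (3.65) and Casp6 at 157 against 19.4 (2.73). The matrix metalloprotease Mmp19 (2.57), Stfa2 (2.22), Cstdc5 (2.19), Csta2 (2.17), the adaptor Lat2 (2.09), coagulation factor X (F10, 2.07; 2.75 without AT3 MHTO8), the cation channel Trpm4 (2.03) and Gchfr, which restrains tetrahydrobiopterin synthesis (2.0), were also higher in all 9 pairs of populations. The inducible nitric oxide synthase Nos2, which is in the myeloid-suppressor list, was at 43.9 CPM (42.6 to 45.4) against 9.35 (8.49 to 10.3), log2 ratio 1.77, higher in all 9 pairs. Ifitm1 was again higher (1.40, and 0.95 without AT3 MHTO7).

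The interferon-stimulated list had a median of -1.06 (-1.04 less all genes, percentile 0), with none of 21 members above 0, 12 at least 2-fold lower and 15 lower in all 9 pairs. Ifi27l2a, outside that list (chromosome 12, 103442167 to 103443680), was at 115 CPM against 732 (-2.62). Ifit3 and its paralog Ifit3b (-2.44 and -2.31, not well separated from each other), Rsad2 (14.6 CPM against 90.4, -2.28), Cmpk2 (-2.10) and Ifit1 (21.3 against 93.7, -1.91) were lower in all 9 pairs, and the ubiquitin-like Isg15 (-1.78) was at -0.97 without AT3 MHTO8 and -2.55 without AT3-gcsf MHTO5. Antigen presentation genes stood at -0.45 (-0.43, percentile 0.94), with B2m at 569.8 CPM against 889 (-0.64) and the immunoproteasome subunit Psmb8 at 96.8 against 142 (-0.53). Without AT3 MHTO8, AT3 MHTO10 or AT3-gcsf MHTO5 that list stood at -0.29, -0.22 and -0.38, inside the central 95%. B cell marker transcripts were at 22.8 to 42.2 CPM in AT3 populations against 8.22 to 15.1 in AT3-gcsf.

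Camp was at 551 CPM against 5375 (-3.27; -1.19 without AT3 MHTO7, -4.04 without AT3-gcsf MHTO4), lower in all 9 pairs. The secondary granule list stood at -1.0 (-0.97, percentile 0) but at -0.34 (percentile 3.04) without the immature-like clusters and 0.18 without AT3 MHTO7, where Ltf went from -1.60 to 0.15 and Ngp from -1.76 to -0.18; the mitotic Ube2c went from -2.09 to -0.36. Ptgs2 (57.8 CPM against 255, -2.05) and Tnfaip3, the NF-kB inhibitor A20 (-1.86), turned to 2.12 and 1.07 without AT3 MHTO8, and were at -2.86 and -2.62 without AT3 MHTO7 and -5.35 and -3.78 without AT3-gcsf MHTO5; Ptgs2 was at -1.46 without AT3-gcsf MHTO4. Bcl2a1b (-1.81) was at 0.43 without AT3 MHTO8, -2.53 without AT3 MHTO7 and -2.61 without AT3-gcsf MHTO5. Leaving out AT3 MHTO8 kept AT3-gcsf MHTO5, which resembled it (Pearson correlation 0.951), in the sums. Ptgs2 was at 719 CPM in AT3 MHTO8 and 145 in AT3-gcsf MHTO5. It was at 17.1 and 5.77 in the other AT3 populations and 1.42 and 1.35 in the other AT3-gcsf ones. The sign changes without AT3 MHTO8, here and for the lists below, thus do not show higher levels in like AT3-gcsf populations. Without AT3 MHTO8 the chemokine (-0.54), NF-kB feedback (-0.52), immediate-early (-0.27) and mature circulating (-0.24) lists were at 1.67, 1.04, 0.76 and 0.19. Their percentiles with all populations were 0.005, 0.070, 1.57 and 0.215. Without AT3-gcsf MHTO5 the first 3 of these were at -1.76, -1.40 and -0.86, and without AT3-gcsf MHTO4 the chemokine, immediate-early and mature circulating lists were at -0.03, 0.10 and -0.04. Without AT3 MHTO7 the NF-kB and immediate-early lists were at -1.42 and -0.89, and without AT3-gcsf MHTO3 the latter was at -0.14. Without the cluster led by Apoe and Siglecf the immediate-early list was at -0.21 (percentile 5.62).

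The lipid list stood at 0.43 (0.46, percentile 99.1), with Apoe at 198 CPM against 63.7 (1.56; 0.56 without AT3-gcsf MHTO4, 0.67 without the cluster led by Apoe and Siglecf) and Plin2 at 393 against 196 (0.99). This call was weak: the list lay inside the central 95% in thinned cells (0.23, percentile 92.8), without the immature-like clusters (0.23, 93.2), with equal weight for the populations (0.29, 97.0), without the cluster led by Apoe and Siglecf (0.27, 97.4) and without AT3 MHTO7 (0.02, 74.3). Glycolysis and hypoxia genes stood at 0.31 (0.34, percentile 99.8), with Pfkl at 44.9 CPM against 21.3 (0.92) and the collagen hydroxylase P4ha1 at 26.6 against 14.4 (0.70); without AT3 MHTO10 the percentile was 97.3. Ageing and clearance genes stood at -0.41 (-0.38, percentile 0.72), with the death receptor Fas at 39.4 CPM against 63.1 (-0.62); with equal weight for the populations the list was at -0.35 (percentile 4.29). Chemotaxis receptors stood at -0.21 (-0.18, percentile 2.29), and at -0.43 (2.56) without AT3 MHTO7 and -0.07 (10.2) without AT3 MHTO10. With computed doublets kept they were at -0.20 (2.58), and without the cluster led by Apoe and Siglecf at -0.23 (2.53). Csf3r was at 769 CPM against 1100.1, Csf3 at 1.34 against 7.0, Ly6g at 704 against 693, and S100a8 and S100a9 at 141249 and 143156 against 155012 and 160204. The other 10 lists lay inside the central 95%: medians were 0.22 for primary granule, 0.12 for oxidative phosphorylation, -0.15 for gelatinase granule, -0.49 for cell cycle, -0.13 for myeloid-suppressor, -0.13 for G-CSF and STAT3 target, -0.12 for NADPH oxidase, -0.13 for apoptosis, -0.17 for transcription factor and -0.10 for protein-folding genes. Of these 10, 9 lay outside that range, on either side, under at least 1 alternative. Cell cycle genes did so under 9 of the 19, at -0.54 and -0.52 without AT3 MHTO8 and MHTO10, -0.57 without AT3-gcsf MHTO4 and -0.90 with a 5 CPM minimum, with medians up to 0.20 over all 19. Myeloid-suppressor genes did so under 6, at -0.73, 1.42 and -0.39 without AT3 MHTO7, MHTO8 and MHTO10, -0.78 without AT3-gcsf MHTO5, -0.31 in thinned cells and -0.27 with equal weights. Only 3 of 10 primary granule and 5 of 20 cell cycle genes were measured, and their medians were the values of Hp and H2afz. Over all singlets, which keep the mixed cluster, the primary granule and cell cycle lists stood at 0.86 and -0.56 (percentiles 99.8 and 1.425).

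In all, 89 of 3542 genes were at least 2-fold higher and 92 lower in AT3-gcsf than in AT3 cells. Of these 181, 119 (65.7%) lay on one side in all 9 pairs, and over genes with any size of difference 21.5% did, where chance gives 10% for genes not picked by size. The median of all genes was -0.03; TMM gave 117 higher and 81 lower, and totals without the 20 most abundant genes 122 and 139. The count was 332 without AT3 MHTO7, 280 without AT3 MHTO8 and 329 without AT3-gcsf MHTO5.

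**Figure D3:**
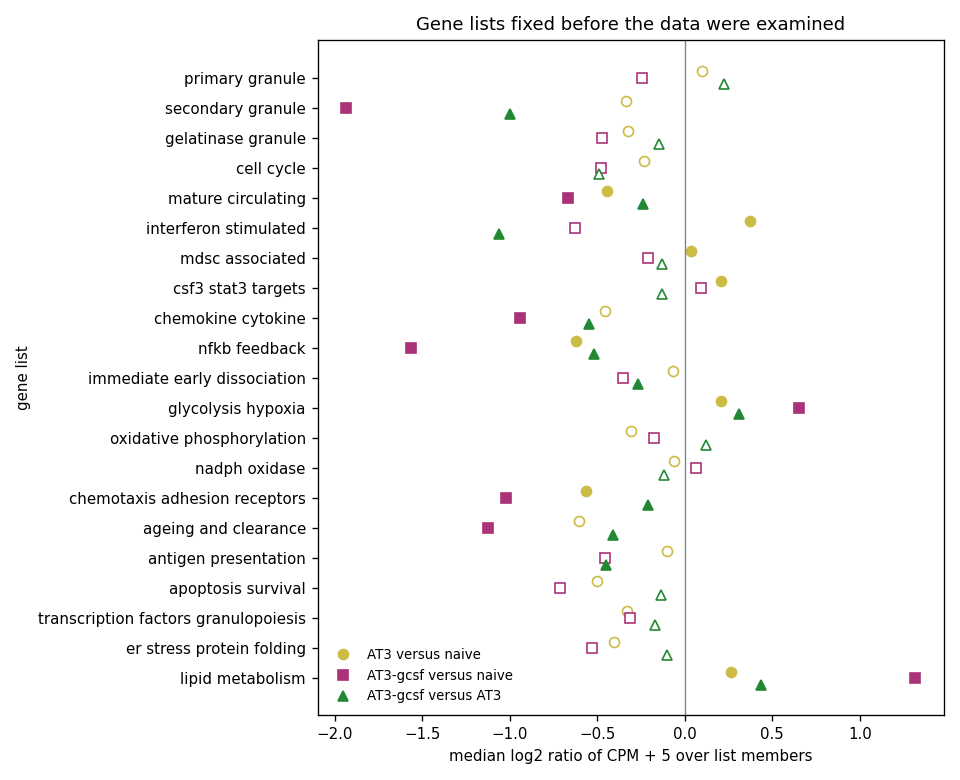
Median log2 ratio of each of the 21 fixed gene lists in the 3 comparisons, 1 point per list and comparison, filled where the median lay outside the central 95% of matched random lists and open where it lay inside. The interferon-stimulated list stood at -1.06 for AT3-gcsf against AT3, and the glycolysis and hypoxia list at 0.21, 0.65 and 0.31 for AT3 against naive, AT3-gcsf against naive and AT3-gcsf against AT3.

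The genes that set AT3 cells apart from naive ones were nearly all among those that set AT3-gcsf cells apart. Of 3920 genes compared in both, 85 were higher in AT3 and 161 in AT3-gcsf, and 76 were shared, against 3.49 for independent lists; Wfdc17, Prok2, Igfbp6, Ifitm1, Ggt1 and Lipg were among the 12 highest of both. Of the lower genes, 238 were shared among 246 and 869, against 54.5 for independent lists, with Thbs1, Olr1, Bcl2a1a and Bcl2a1b among the 12 lowest of both. Both comparisons used the same naive library, so part of the excess can come from the shared control; 100 simulations of counting error alone gave 0 shared genes, which such deep sums make certain, so they say nothing about differences of the naive mice or lane. Under TMM, 172 of 182 genes higher in AT3 were shared with 438 in AT3-gcsf, and 35 of 38 lower ones with 270. Without naive MHTO4, 105 of 125 and 649 of 694 were shared, and without naive MHTO5, 139 of 175 and 281 of 290. Without AT3 MHTO8, 61 of 73 and 314 of 448 were shared, and without AT3 MHTO10, 67 of 75 and 357 of 392. The ratios of the 4 lower genes named depended on naive MHTO5, which both comparisons share. Without it, Thbs1, Olr1, Bcl2a1a and Bcl2a1b were at -0.78, -0.07, -0.43 and 1.09 in AT3. In AT3-gcsf they were at -2.41, -1.0, -1.39 and -0.72. Like populations stayed on the other side, since AT3 MHTO8 and AT3-gcsf MHTO5 shared 237 and 172 raised genes with naive MHTO5. Thbs1 was at 4231 CPM in naive MHTO5 and 242 in AT3 MHTO8. The other naive populations had 182 and 100.4 CPM, and the other AT3 ones at most 6.94. Ratios without naive MHTO5 therefore do not show that like populations had like levels.

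Transcripts of other cell types and of mitochondria differed between the libraries. Erythroid markers summed to 89.9 to 1300.0 CPM in naive populations, 28.0 to 820.4 in AT3 and 0.187 to 0.258 in AT3-gcsf, and lung endothelial, epithelial and stromal markers to 116 to 233, 82.5 to 148 and 32.3 to 36.2. Macrophage markers, which include Apoe, summed to 510 to 1204 CPM in naive, 785 to 1125 in AT3 and 1023 to 1836 in AT3-gcsf populations, and eosinophil markers to 271 to 729, 278 to 656 and 417 to 427. The club-cell secretory gene Scgb1a1 was at 133 CPM in naive, 88.1 in AT3 and 23.7 in AT3-gcsf cells. Mitochondrial transcripts took 0.339%, 0.749% and 1.46% of the counts of the naive, AT3 and AT3-gcsf cells, and S100a8 with S100a9 took 25.4%, 31.5% and 28.4%. The share of S100a8 with S100a9 ran from 12.5% to 37.3% over naive, 25.2% to 39.4% over AT3 and 27.0% to 29.6% over AT3-gcsf populations.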

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

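The test of the mix of tagged populations was chosen after the result was seen; the other 4 were set down before their statistics were computed, though related values had been looked at.

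Many more genes differed 2-fold between AT3-gcsf and naive cells (1093) than between AT3 and naive cells (331). Without naive MHTO4 the counts were 1443 and 828, a ratio of 1.74 against 3.30 with all populations. Without AT3 MHTO8 the AT3 count was 521, with the AT3-gcsf count unchanged at 1093. Deeper cells in the AT3-gcsf library would make the counts alike once every cell is thinned to the same number of counts, but the ratio of the counts was then 3.29. Large sums scaled to their total change little when cells are thinned, so this test cannot decide the question. It shows only that giving deep cells no more weight than others left the ratio nearly unchanged. Unequal shares of the tagged populations in the sums would bring the counts together once the populations of a library are given equal weight, but their ratio was 3.23. Equal weights cannot supply a population that a library lacks. Camp was at most 957 CPM in AT3-gcsf populations, against 21134 in naive MHTO4 and 10586 in AT3 MHTO7. Immature neutrophil markers, which include Camp, summed to 29149 to 39730 CPM in AT3-gcsf populations. They summed to 91970 CPM in naive MHTO4 and 79988 in AT3 MHTO7, but to 16750 and 10162 in naive MHTO3 and MHTO5. Camp alone thus cannot show that AT3-gcsf lacked such a population. A different mix of populations stays open. The ratio of 1.74 without naive MHTO4 cannot decide this, because AT3 MHTO7, which shared 88 raised genes with naive MHTO4, stayed in the AT3 sum. The AT3-gcsf count exceeded the AT3 count by 615 genes there, against 762 with all populations. The mix of cell states within a population stays open, and an effect of the AT3-gcsf tumour and an effect of its lane, capture day or mice cannot be told apart, because that condition filled 1 lane. The counts may therefore mix biology with a difference between lanes.

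The mitochondrial share drew attention because its median per cell was 0.667% in AT3 and 1.42% in AT3-gcsf, against 0.250% in naive cells. A minority of damaged cells would leave the lower part of the AT3-gcsf cells at the naive level, but their 10th percentile, 0.884%, lay above the naive median. More counts per cell would remove the difference among cells with 3000 to 6000 counts, but the ratio of the AT3-gcsf to the naive median was 6.08 there. A change of mitochondrial transcription or content, stress of all cells during sorting, and lane chemistry stay open and cannot be told apart in this design. Any of them could raise all cells alike.

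The interferon-stimulated list was lower in AT3-gcsf than in AT3 (median log2 ratio -1.06). Against naive it stood at 0.37 in AT3 (percentile 100 among matched lists; -0.22 and 98.7 without naive MHTO4) and at -0.63 in AT3-gcsf (percentile 10.9, but below the central 95% under 5 of 19 alternatives). More cells of the immature-like clusters would bring the median near 0 once these are left out, but it stood at -1.25. More interferon signalling in mice with AT3 tumours, less in mice with AT3-gcsf tumours, or both stay open. No biological explanation was tested, since the lane and anything else that went with condition cannot be told apart from the tumour.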

How the results depend on the processing

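Leaving out populations, equal weights, leaving out the cluster led by Apoe and Siglecf, counting only genes on one side in all 9 pairs, and the genes shared by both comparisons against naive under any alternative were chosen after the result was seen; the other alternatives were planned. The tissue test with edgeR and its alternatives (DESeq2, no filter, no block, leaving out each condition, all singlets, the 80% rule, mature clusters) were not run, because hashtag names give no tissue. Depth limits genes of low level: the 20 CPM minimum leaves most genes of the annotation uncompared, and 425, 83 and 113 naive, AT3 and AT3-gcsf cells had fewer than 1500 counts before thinning. The direction of a list was counted as its side of matched random lists, so some medians changed sign and kept their side: the interferon list in AT3 v naive was -0.22 without naive MHTO4 (percentile 98.7), and mature circulating genes were at 0.08 under TMM. Over the 19 alternatives that apply, the interferon (AT3 v naive, AT3-gcsf v AT3), glycolysis (both against naive), lipid and ageing lists (AT3-gcsf v naive) stayed outside the central 95% on their side. Of 36 list comparisons inside the central 95%, 30 lay outside it under at least 1 alternative. The cause of the changes below was not tested, except for the pseudocount, which shrinks ratios of low genes by construction, and the count of genes in all 9 pairs, a subset by construction. Leaving out a population shifts the genes that mark it by construction where a like population stays on the other side. Pearson correlations were 0.933 for naive MHTO4 and AT3 MHTO7, 0.916 for naive MHTO5 and AT3 MHTO8, and 0.951 for AT3 MHTO8 and AT3-gcsf MHTO5. Leaving out the immature-like clusters likewise takes out cells picked by markers that overlap the secondary granule list.

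With 20 CPM added, 129, 610 and 87 genes differed 2-fold in AT3 v naive, AT3-gcsf v naive and AT3-gcsf v AT3. Only genes on one side in all 9 pairs numbered 163 in AT3 v naive and 119 in AT3-gcsf v AT3. Single-tag cells made up 94.7% in AT3 at a stricter quantile, and 95.7%, 97.4% and 94.1% in naive, AT3 and AT3-gcsf under the 80% rule.

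Values below are log2 ratios, or list medians, in the order of the comparisons. Without the immature-like clusters, AT3 v naive: Elane 0.16, Chil3 0.39, Orm1 0.51; AT3-gcsf v naive: secondary granule 0.88, Serpinb1a 0.42, Ngp 0.65. Cebpe was at 0.0245 in AT3-gcsf v AT3.

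Without the naive population MHTO4, AT3 v naive had 828 genes, with the myeloid-suppressor list at -0.57, G-CSF and STAT3 targets -0.51, Elane 0.0904, Cybb 1.61, Chil3 2.22, Orm1 0.90 and Cebpe 0.80. AT3-gcsf v naive had secondary granule 1.52, Elane 0.10, Serpinb1a 1.64, Cybb 0.11, Ngp 1.72 and Klf5 0.14.

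Without the naive population MHTO5, AT3 v naive had mature circulating 0.25, NF-kB feedback 1.24, Bcl2a1b 1.09, Bcl2a1d 0.75, Tgm2 0.79, Ccl3 0.89, Icam1 0.93, Vegfa 0.42, Cxcl3 2.15 and Cd80 0.10. AT3-gcsf v naive had chemokines 1.69, NF-kB feedback 0.80, Nr4a3 0.19, Ccl3 0.70, Osm 1.13, Vegfa 0.0492, Tnfaip3 0.59 and Fosb 1.88.

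Without the AT3 population MHTO7, NF-kB feedback was at 0.11 in AT3 v naive. AT3-gcsf v AT3 had 332 genes, secondary granule 0.18, Serpinb1a 0.30, Ltf 0.15, Cybb 0.10 and Cebpe 0.38.

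Without the AT3 population MHTO8, AT3 v naive had 521 genes, myeloid-suppressor -1.12, G-CSF and STAT3 targets -0.34 and Hilpda -2.0. AT3-gcsf v AT3 had 280 genes, mature circulating 0.19, chemokines 1.67, NF-kB feedback 1.04, immediate-early 0.76, Ptgs2 2.12, Tnfaip3 1.07, Bcl2a1b 0.43, Thbs1 1.58, Nfkbie 1.01 and Fos 0.94.

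Without the AT3-gcsf population MHTO4, the immediate-early list was at 0.10 in AT3-gcsf v AT3. Without the AT3-gcsf population MHTO5, Hilpda was at -1.48 in AT3-gcsf v naive; AT3-gcsf v AT3 had 329 genes, Ccl2 -0.68, Ccl4 -0.68 and Hilpda -2.49.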

Other observations

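The granule genes did not move in step between the libraries. Camp stood at 67.9%, 86.6% and 81.2% of Ngp in the naive populations MHTO3, MHTO4 and MHTO5, at 57.1%, 34.6% and 45.1% in the AT3 populations MHTO7, MHTO8 and MHTO10, and at 17.5%, 24.4% and 9.60% in the AT3-gcsf populations. Ltf kept a narrower range, 25.7% to 27.8% of Ngp in naive, 22.2% to 26.8% in AT3 and 24.3% to 31.9% in AT3-gcsf populations. Lcn2 went the other way, with 49.4% to 214.8% of Ngp in naive, 80.7% to 188.7% in AT3 and 245% to 379% in AT3-gcsf populations, so that AT3 lay within the naive range. These ratios lie within a population and do not depend on scaling, but they were chosen after the data were seen.

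The clusters divided mostly by library. The cluster led by Camp, Ltf and Ngp held 1021 naive, 751 AT3 and 29 AT3-gcsf cells, and the other immature-like cluster, led by Cstdc5, Stfa3 and Stfa1, held 6, 311 and 2430. The cluster led by Ifit1 and Ifit3 held 227, 3067 and 166 cells, the one led by Ptgs2 and Ccrl2 58, 2412 and 70, and the one led by Thbs1 and Bcl2a1b 2120, 37 and 0. The clusters led by Hilpda and Areg (14, 249 and 3432), by Saa3 and Tagln2 (1, 57 and 1984) and by Apoe and Mif (3, 40 and 1781) were mostly AT3-gcsf. Platelet markers summed to 7.92 to 123.6 CPM in naive populations and 0.981 to 1.80 in AT3-gcsf ones, and T and NK cell markers to 23.7 to 32.8 against 1.07 to 1.42.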
